A study of Mus musculus with 6 samples.

How the data were processed

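The samples were 6 Drop-seq libraries of adult mouse heart cells after Langendorff digestion, 3 from Control and 3 from YAP5SA hearts. In each genotype 2 libraries came from dissociated tissue, with the cardiomyocyte and other fractions put together again, and 1 from cardiomyocytes enriched by gravity settling. Picard, STAR and Seurat 2.3.4 were used upstream, per the submitters' processing notes, which give no settings, genome build or annotation. The deposited table of raw data holds UMI counts of 22281 features in 21706 cells, and every value is a whole number of 0 or more. The deposited table of cells gives the library, the authors' 17 clusters, a cell cycle phase call and percent.mito, the fraction of a cell's UMIs on mitochondrial genes as computed by the authors. A table of scaled values was not used, since it holds no counts. The total per library ran from 3382656 to 13483791 UMIs and limits the precision of each value; intervals for shares of cells are exact Clopper-Pearson intervals at 95%, and a count of 0 was taken to allow up to 3 counts.

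In 4 libraries the names of overlapping genes are joined by hyphens, and in the other 2 they are not. The 856 joined names were merged with their members (693 families, 21297 features), and 1247 features with counts under 1 way of annotation alone were not tested; these held 0.174% and 0.255% of the UMIs of the libraries with and without joined names. The 17 clusters were put into 8 classes by name: CM1 to CM3 and YAP5SAcm as cardiomyocytes, CF1 to CF4 as fibroblasts, Mac1 to Mac4 as macrophages, and monocytes, endothelial, endocardial, epicardial and smooth muscle cells as 1 cluster each. Counts were summed per library and class, and a library entered with at least 10 cells of the class. Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, quasi-likelihood F test with robust dispersion, preparation and genotype as terms), at a Benjamini-Hochberg adjusted p of 0.05. Differences of the genotype effect between cardiomyocytes and another class were tested with the class by genotype term in a model with the library as a block. Positive fold changes mean higher in YAP5SA.

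Of 36 gene lists, 20 covered pathways: YAP targets, Hippo components, S phase, G2/M phase, G1 regulators, mature sarcomere, fetal cardiac, actin cytoskeleton, nuclear oxidative phosphorylation, mitochondrially encoded, fatty acid oxidation, glycolysis, complement, cytokine, matrix, interferon, immediate early, antioxidant, unfolded protein response and ribosomal protein genes. The other 16 held markers of cell types: cardiomyocyte, fibroblast, endothelial, endocardial, lymphatic endothelial, macrophage, monocyte, neutrophil, T or NK cell, B cell, pericyte, smooth muscle, epicardial, Schwann cell, erythroid and adipocyte. Lists with at least 3 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), and with an estimated correlation and fry beside it, adjusted over the pathway or the marker lists of a class. Genes were named by a rule: in cardiomyocytes Yap1, the 10 largest and 10 smallest log2 fold changes among genes that passed, had an average log2 CPM of at least 5 and moved the same way in both preparations, and the 3 members of each pathway list with the smallest p; in other classes the 5 largest and 5 smallest and 2 members of each list called. Genes whose mean level in the class was more than 5-fold below that in another class with at least 100 cells were left out of the largest and smallest, 82 raised and 12 lowered in cardiomyocytes. Nppa, Acta1 as a value per library, and Egfp lie outside this rule and were chosen after their values were seen. The comparisons, tests, lists, naming rule and the other settings of each test were chosen before the data were examined. Merging joined names and the alternatives that depend on it, on pseudogenes or on the cluster YAP5SAcm were chosen after.

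Shares of cells per class were compared with an exact two-sided permutation test of the difference of means, with genotype permuted within preparation, which has 12 arrangements and a smallest p of 0.167. For cell cycle transcripts each cell was thinned to 1000 UMIs, the highest of the depths tried that kept at least 70% of the cardiomyocytes of every library (the lowest kept was 83.97%), and cells with a UMI of 43 S phase or 54 G2/M phase genes were counted. Processed pseudogenes were taken by symbol from GENCODE vM21, which gave a gene type for 20254 features and is not known to be the annotation the authors used. Alternatives were RLE size factors, library totals alone, DESeq2 1.42.0, no filter on low counts, no covariate, tissue libraries alone, equal numbers of cells, at least 30 cells, each library left out in turn, and doublets removed with scrublet (scanpy 1.11.5). Scrublet marked 0.0686% to 0.468% of cells per library, too few to have found the doublets of such libraries, so doublets remain in the data. Sums, shares and thinning used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

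The procedure was tested on simulated data with 200 changed genes in the sizes and spread of these libraries. In cardiomyocytes edgeR recovered 3% of 2-fold, 59.7% of 4-fold and 92.4% of 8-fold changes, and in the other classes 1.5% to 25.4%, 41.8% to 77.6% and 84.8% to 98.5%. For differences of the effect from cardiomyocytes it recovered 7.5%, 40.3% and 74.2% in fibroblasts, 3%, 25.4% and 66.7% in macrophages, and 1.5%, 37.3% and 74.2% in endothelial cells. With the G2/M genes raised 2-fold, camera gave adjusted p = 6.98e-29 with the preset and 0.0263 with an estimated correlation, and called 0 of 19 other lists. Splits of the real cardiomyocyte libraries that mix the genotypes called 9 to 15 lists with the preset, against 17 by genotype. The simulated 0 of 19 therefore gives no rate of false calls with the preset in the real libraries.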

Results

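Single-cell RNA profiles were collected by Drop-seq, which barcodes the 3' ends of the transcripts of single cells in droplets, from adult mouse hearts after tamoxifen. Control mice carried Myh6-MerCreMer, a tamoxifen-activated Cre recombinase expressed in cardiomyocytes. YAP5SA mice carried in addition a transgene for a form of YAP, the transcriptional coactivator of the Hippo pathway, that the Lats kinases cannot phosphorylate. Each genotype had 3 libraries, 2 from dissociated heart tissue and 1 from enriched cardiomyocytes. The 6 libraries held 21706 cells and 50784032 UMIs in all. Control enriched held 1405 cells and 3382656 UMIs, Control tissue-2 2914 cells and 6793317 UMIs, and Control tissue-3 3116 cells and 10568669 UMIs. YAP5SA tissue-1 held 3845 cells and 6665280 UMIs, YAP5SA tissue-2 5860 cells and 13483791 UMIs, and YAP5SA enriched 4566 cells and 9890319 UMIs. The median per cell ran from 1323 UMIs in Control tissue-2 to 1897.5 in YAP5SA tissue-2. Cardiomyocytes numbered 1068, 576 and 1173 in the Control libraries in that order, mostly in the authors' clusters CM1, CM2 and CM3. They numbered 343, 282 and 1004 in the YAP5SA libraries, where the cluster YAP5SAcm was the largest. Their median depth was 2204, 4595 and 4565 UMIs per cell in Control and 1876, 2679.5 and 2698 in YAP5SA. Control enriched, Control tissue-2, YAP5SA tissue-1 and YAP5SA tissue-2 join the names of overlapping genes into 1 feature and the other 2 libraries do not. The libraries were thus annotated in 2 ways, both found in each genotype.

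The first comparison asked what the activated YAP did to the transcriptome of adult cardiomyocytes, the question named in the title of the series. YAP5SA cardiomyocytes held more RNA of many cell division and YAP target genes, and less RNA of many contractile, respiratory and fat-burning genes. Of 20 pathway lists camera called 17 with its preset correlation and 0 with an estimated one. Mki67, a marker of cycling cells, went from 2.12 ± 1.75 to 68.4 ± 29.2 CPM (counts scaled to library size and by TMM, mean ± SD, n = 3 libraries each), and Anln, a scaffold of the ring that divides cells, from 0.817 ± 0.447 to 41.4 ± 16.5 CPM. Csf1, the growth factor of macrophages, went from 21.2 ± 4.85 to 329.7 ± 114 CPM. Tnni3, cardiac troponin I, fell from 14083 ± 6526 to 1704 ± 755 CPM, and Sdhb, a subunit of respiratory complex II, from 3418 ± 1215 to 496 ± 252 CPM. In edgeR's test on counts summed per library, 2889 of 10922 genes passed an adjusted p of 0.05, 1518 higher and 1371 lower in YAP5SA. Of these, 2837 had no overlap between the libraries of the genotypes, against 48.1% of all genes tested and 10% by chance. The count was 1763 in the tissue libraries alone, 1183 in the 4 libraries with joined names, and 4543 (4121 higher and 422 lower) with library totals alone as scaling, which moves the median log2 fold change of all genes from 0.04 to 0.88. It was 17 without the cells of the cluster YAP5SAcm, which the authors drew from the same transcripts. Leaving out 1 library gave 198 genes (194 higher and 4 lower) without YAP5SA tissue-2, 538 (464 and 74) without YAP5SA tissue-1, and 1591 without YAP5SA enriched. It gave 1578 without Control enriched, 1598 without Control tissue-3 and 4595 without Control tissue-2.

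Yap1 itself had 21.5 ± 1.20 CPM in Control and 30.4 ± 8.58 CPM in YAP5SA (log2 fold change 0.46, SE 0.29, edgeR adjusted p = 0.275, n = 3 libraries each), and did not pass the test. This rests on the scaling: with library totals alone Yap1 passed at 1.30 (edgeR adjusted p = 0.018), with 15.3, 17.9 and 14.8 CPM (unscaled) in Control enriched, tissue-2 and tissue-3 and 52.9, 46.0 and 24.6 in YAP5SA tissue-1, tissue-2 and enriched. Unless a unit stands beside it, a value given after a gene's name or for a list is a log2 fold change, YAP5SA against Control. The labels do not say whether transcripts of the transgene end in a sequence counted as Yap1, so this value does not check the genotypes. Among genes not more than 5-fold below their level in another class of at least 100 cells, a rule that limits free RNA of other cells without excluding it, Cemip, which takes part in breaking down hyaluronan, rose most. It had no UMI in the Control cardiomyocytes and 2421 in YAP5SA, at least 935-fold higher against a floor of 3 counts over the Control group. Pak3, a kinase downstream of Rac and Cdc42, rose by 7.27 on the log2 scale, Col4a4, a basement membrane collagen, by 6.88, Mcam, an adhesion molecule, by 6.30, and the integrin subunit Itga3 by 4.65. Plcxd2, Serpinb9b, Fam107b, Col12a1 and Pmp22 rose by 7.25, 6.52, 5.90, 5.59 and 4.86. Of the genes that fell most, Acadm, the medium-chain acyl-CoA dehydrogenase, went from 3683 ± 2535 to 307 ± 165 CPM, a log2 change of -3.64, and Rxrg, a retinoid X receptor, changed by -3.63. Esr1, the estrogen receptor gene whose ligand-binding domain is part of MerCreMer, changed by -5.37. Its level within Control was 888 CPM (unscaled) in the enriched library, 700.2 in tissue-3 and 32.0 in tissue-2, the last within the range of YAP5SA tissue-1, tissue-2 and enriched (30.2, 4.76 and 41.5). Other values of Control tissue-2 run both ways. Its cardiomyocytes held 7688 CPM (unscaled) of Nppb, near the 5068 to 6543 of YAP5SA, against 614 and 343 in Control enriched and tissue-3. Its median mitochondrial share over all cells was 2.31%, against 13.4% and 16.0% in these 2 libraries and 2.40% to 6.60% in YAP5SA. Nearer to Control were its cell cycle genes and its cells in the cluster YAP5SAcm. The S and G2/M genes that rose stood together at 132 CPM (unscaled) in its cardiomyocytes, 87.1 and 83.8 in Control enriched and tissue-3, and 1855, 2012 and 1150 in YAP5SA tissue-1, tissue-2 and enriched. Of its 576 cardiomyocytes 50 lay in the cluster YAP5SAcm, against 16 of 1068 and 33 of 1173 in Control and 212 of 343, 203 of 282 and 481 of 1004 in YAP5SA. Whether it is of another line or age cannot be told from the files, and without it 4595 genes passed in place of 2889. Ttll1, Yipf7, Asb10, Adhfe1, Gm34302, Ift81 and Tuba8 changed by -5.60, -4.65, -4.27, -4.24, -3.87, -3.84 and -3.80. Of the 74 named genes that passed, all kept their direction with edgeR's other scalings and with DESeq2, and 71 had no overlap between the genotypes' libraries. Of these genes 26 still passed without YAP5SA tissue-2 and 39 without YAP5SA tissue-1, and all kept their direction in the 4 libraries with joined names, with 48 called.

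**Figure D1:**
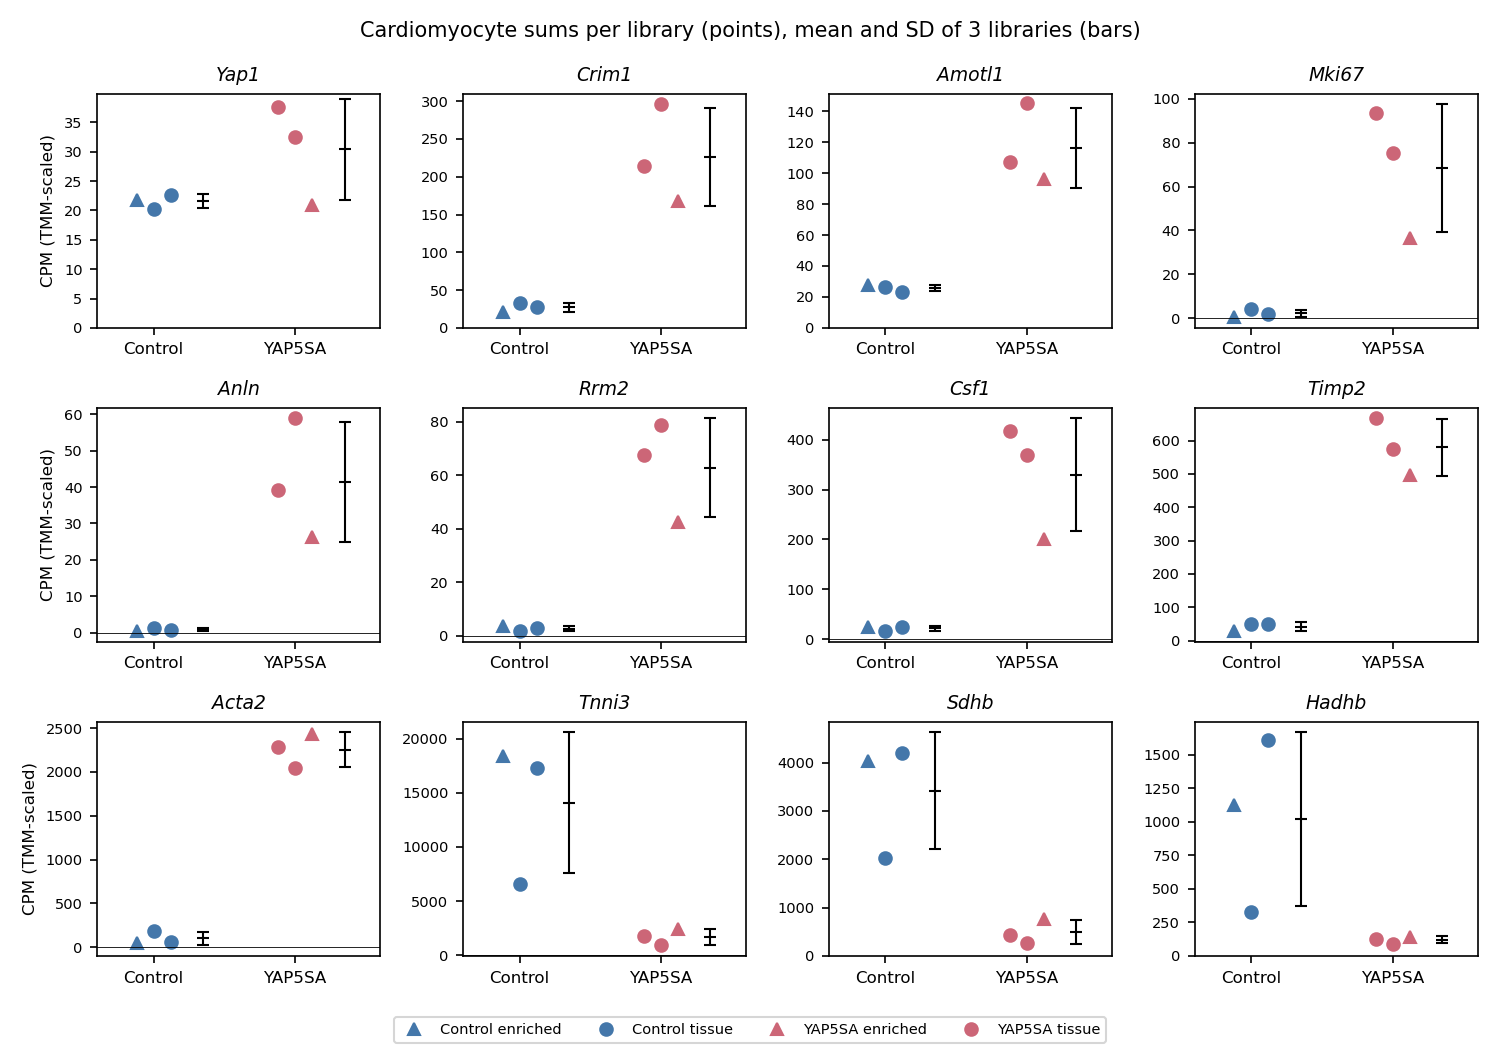
TMM-scaled CPM of 12 genes in the summed cardiomyocytes of each library, with tissue libraries as circles, enriched ones as triangles, and the mean and SD of 3 libraries per genotype as bars. The YAP5SA libraries lie above all Control libraries for Crim1, Amotl1, Mki67, Anln, Rrm2, Csf1, Timp2 and Acta2, below them for Tnni3, Sdhb and Hadhb, and overlap them for Yap1.

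Many genes of the cell cycle rose. Of 50 G2/M phase genes, 38 rose and 1 fell (40 up and 1 down adjusted over the list alone), with a median log2 fold change of 4.29, which stays the same with the 2 members that had no UMI in Control at their lower bound. Mki67 rose by 5.07, Anln by 5.66 and Cenpe, a motor protein of the kinetochore, by 4.75. Of 37 S phase genes, 17 rose and 3 fell (18 up and 3 down adjusted over the list alone), with a median of 1.61. Among them were Rrm2, a subunit of ribonucleotide reductase (4.52), and the replicative helicase subunits Mcm6 (4.74) and Mcm5 (3.98). Of 15 G1 cyclins and regulators, 7 rose and 0 fell (7 up and 1 down adjusted over the list alone). The transcription factor E2f1 stood at 6.33, cyclin D1 (Ccnd1) at 2.21 and the inhibitor Cdkn1c, which acts against the cycle, at 2.60. Each of these 9 genes lay more than 5-fold below its level in another cell class of the same hearts. Of 14 macrophage markers 3 rose in YAP5SA cardiomyocytes too, with a median log2 fold change of 1.74 over the 14. As a list they were called by camera with its preset correlation but not with an estimated one. In cardiomyocytes without a UMI of 27 macrophage and fibroblast markers the 55 S and G2/M genes that rose stood together at 963, 2192 and 865 CPM in YAP5SA tissue-1, tissue-2 and enriched (92, 49 and 545 UMIs in 61, 16 and 312 cells). They stood at 82.2, 119 and 83.6 CPM in Control enriched, tissue-2 and tissue-3 (192, 28 and 88 UMIs in 885, 102 and 299 cells). The 55 genes were picked as higher in the same libraries, which favours such a gap. Without YAP5SA tissue-2 13 G2/M and 2 S phase genes rose, and without YAP5SA tissue-1 25 and 7. Over the S and G2/M genes together the median was 2.99 in the 4 libraries with joined names, of which only a Control one is enriched. It was 1.83 between the other pair, Control tissue-3 and YAP5SA enriched, 1 library each, which differ in preparation too. By camera with its preset correlation the lists had adjusted p = 1.70e-16 for G2/M, 1.43e-06 for S and 0.000871 for G1. Each had adjusted p = 0.114 with an estimated correlation. Without the cells of the cluster YAP5SAcm the S phase list had a median of -0.14 and was no longer called (camera adjusted p = 0.644), which decides nothing, since the authors drew the cluster from the same transcripts.

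**Figure D2:**
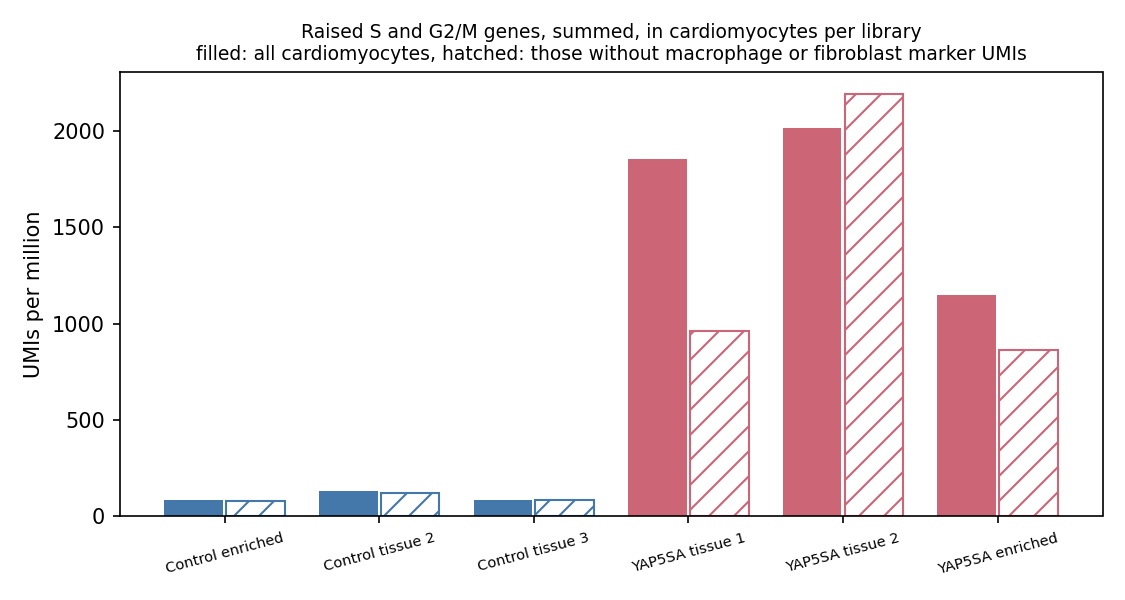
Unscaled CPM of the S and G2/M genes that rose, summed per library, in all cardiomyocytes (filled bars) and in those without a UMI of 27 macrophage and fibroblast markers (hatched bars). Without such a UMI the 3 YAP5SA libraries stand at 865 to 2192 and the 3 Control libraries at 82.2 to 119. The genes were picked as higher in the same libraries, which favours such a gap.

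Many genes of YAP's own pathway rose. Of 20 YAP target genes, 13 rose and 0 fell (15 up and 0 down adjusted over the list alone), with a median log2 fold change of 2.71. Crim1, a transmembrane protein that binds BMPs, went from 27.1 ± 5.88 to 226 ± 64.7 CPM (log2 fold change 3.06, SE 0.30, edgeR adjusted p = 0.00228, n = 3 libraries each). Axl, a receptor tyrosine kinase, rose by 3.58, and Asap1, a GTPase-activating protein for Arf, by 2.72. Of 15 components of the Hippo pathway, 7 rose and 0 fell (9 up and 0 down adjusted over the list alone). The angiomotins Amot (5.91) and Amotl1 (2.16), which bind YAP, and Tead4 (4.67), one of the transcription factors that carry YAP to DNA, had the smallest p. Amot and Tead4 stood at 0.361 CPM each in Control, and Axl lay more than 5-fold below its level in another class. The camera adjusted p was 9.24e-08 for the targets and 0.000195 for the Hippo components, and 0.114 for each with an estimated correlation.

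Many genes of the mature, beating cardiomyocyte fell. How many depends on the scaling: with library totals alone 422 genes of all kinds were called lower, in place of 1371. The median log2 fold change of all genes was 0.88 there, in place of 0.04. Of 25 sarcomere and calcium handling genes, 11 fell and 0 rose (0 up and 15 down adjusted over the list alone), with a median log2 fold change of -1.37. Pln, phospholamban, the brake of the calcium pump, changed by -3.48, Tnni3 by -3.07 and Ckm, muscle creatine kinase, by -2.87. Of 45 nuclear genes of oxidative phosphorylation, 44 fell and 0 rose (0 up and 44 down adjusted over the list alone), with a median of -2.14. Ndufa9, Sdhb and Cyc1, subunits of complexes I, II and III, changed by -2.38, -2.88 and -2.43. Of 23 genes of fatty acid oxidation, 19 fell and 0 rose (0 up and 19 down adjusted over the list alone), with a median of -2.37. The beta-oxidation enzymes Hadhb, Hadh and Echs1 changed by -3.09, -2.98 and -2.77. Of 20 glycolysis genes, 8 fell and 1 rose (1 up and 9 down adjusted over the list alone), including the muscle forms Pfkm (-2.72), Eno3 (-2.63) and Pgam2 (-2.09). The 9 mitochondrially encoded genes had a median of -1.29 and none passed by edgeR, over all genes or adjusted over the list alone. The values were, for mt-Nd6, -1.73 (adjusted p = 0.0587), for mt-Cytb -1.48 (0.0650) and for mt-Nd5 -1.60 (0.0705). Over all cells the median share of mitochondrial UMIs was 13.4% in Control enriched and 16.0% in Control tissue-3, but 2.31% in Control tissue-2, near the 2.95% and 2.40% of YAP5SA tissue-1 and tissue-2, and 6.60% in YAP5SA enriched. Without Control tissue-3 the list's median was -0.76. Without YAP5SA tissue-2, or without YAP5SA tissue-1, no member of the sarcomere, oxidative phosphorylation, fatty acid oxidation and glycolysis lists was called lower by edgeR, with 3043 and 3390 of all genes at an unadjusted p under 0.05. So these single calls need both libraries. The medians of the lists stayed at -1.42, -1.96, -2.19 and -0.90 in that order without YAP5SA tissue-2. Of the fatty acid oxidation genes 1 was called lower without Control enriched and 1 without YAP5SA enriched. The camera adjusted p was 9.73e-09 for the sarcomere list, 5.03e-19 for oxidative phosphorylation, 1.76e-08 for fatty acid oxidation, 0.000845 for glycolysis and 0.00161 for the mitochondrially encoded genes. The lists had, in that order, adjusted p = 0.114, 0.456, 0.466, 0.116 and 0.466 with an estimated correlation. In Control tissue-2 the cardiomyocytes held 29682 CPM (unscaled) of Nppa and 4571 of Acta1, genes of fetal and stressed heart muscle. These were 371 and 183 in the enriched and 334 and 143 in the tissue-3 library of the same genotype.

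Some genes of the cytoskeleton, the matrix and signalling also rose in YAP5SA cardiomyocytes, fewer than 1 in 2 of each list. Of 32 actin cytoskeleton genes, 12 rose and 0 fell (14 up and 0 down adjusted over the list alone). Among them were S100a6 (5.49), the scaffold Ahnak (2.61) and Ezr, ezrin (2.38). Of 14 fetal cardiac genes, 4 rose and 1 fell (5 up and 1 down adjusted over the list alone). The members with the smallest p were Acta2, smooth muscle actin, which went from 100.1 ± 77.6 to 2256 ± 198 CPM, Tagln, transgelin (4.91), and Myh9, a non-muscle myosin (3.66). Of 35 extracellular matrix genes, 10 rose and 0 fell (11 up and 0 down adjusted over the list alone). Lox, which crosslinks collagen, stood at 6.44, Thbs1, thrombospondin, at 5.31 and Timp2, a metalloproteinase inhibitor, at 3.81. Of 20 cytokines and chemokines, 5 rose and 1 fell (5 up and 1 down adjusted over the list alone). Csf1 stood at 3.91, Tgfb3 at 4.63 and Igf1 at 2.94. Of 12 complement genes, 4 rose and 0 fell (4 up and 0 down adjusted over the list alone). C1ra, a protease of the classical pathway, stood at 4.28, Cd55 at 2.05 and Cfp, properdin, at 2.02. Of 27 interferon response genes, 5 rose and 0 fell (5 up and 0 down adjusted over the list alone). The peptide transporter Tap1 stood at 3.54, Ifit2 at 1.95 and H2-K1 at 1.68. S100a6, Ezr, Tagln, Myh9, Lox, Thbs1, Timp2, Igf1, C1ra, Cd55, Cfp, Tap1, Ifit2 and H2-K1 lay more than 5-fold below their level in another class, while Csf1, Tgfb3, Acta2 and Ahnak did not. Markers of macrophages, smooth muscle and epicardium had medians of 1.74, 0.87 and 3.18 in the same fit, so RNA of other cells was not told apart. The camera adjusted p of these lists was 3.58e-06 for actin, 0.0135 for fetal, 1.07e-07 for matrix, 0.0205 for cytokine, 0.0130 for complement and 0.000871 for interferon genes. In that order they had adjusted p = 0.466, 0.466, 0.462, 0.532, 0.496 and 0.496 with an estimated correlation. Without Control enriched the fetal, complement, cytokine and interferon lists were no longer called (camera adjusted p = 0.0826, 0.190, 0.154 and 0.0516). Without YAP5SA enriched the fetal, complement and cytokine lists were not (0.0875, 0.118 and 0.170).

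**Figure D3:**
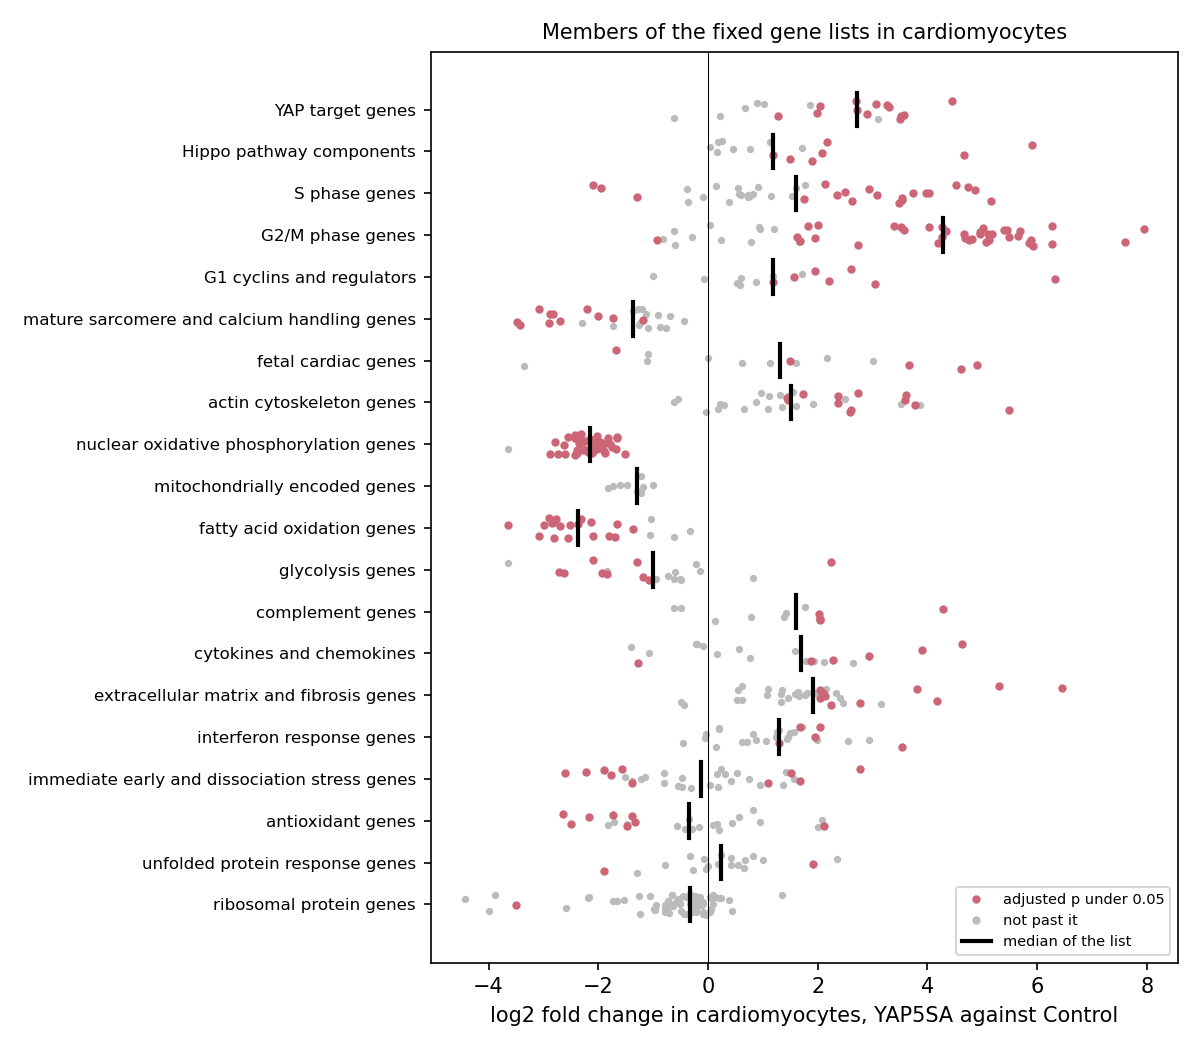
Log2 fold change in cardiomyocytes, YAP5SA against Control, of every tested member of the 20 gene lists, red where edgeR's adjusted p is under 0.05 and grey where not, with the median of each list as a black bar. The G2/M list has the highest median, 4.29, and the fatty acid oxidation list the lowest, -2.37.

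Immediate early, antioxidant and unfolded protein response genes showed no common direction past the test in cardiomyocytes. Of 32 immediate early genes, 4 rose and 6 fell (5 up and 7 down adjusted over the list alone). Fosl2 stood at 2.76, and Jun and the antiproliferative Btg2 at -2.60 and -2.22. Of 25 antioxidant genes, 1 rose and 7 fell (1 up and 9 down adjusted over the list alone). Txnrd1, thioredoxin reductase, rose by 2.11, and the mitochondrial enzymes Sod2 and Prdx3 changed by -2.65 and -2.17. Of 19 unfolded protein response genes, 1 rose and 1 fell (1 up and 1 down adjusted over the list alone), Chac1 at 1.92 and Herpud1 at -1.90. Ddit3 had -1.30 (edgeR adjusted p = 0.0512). The camera adjusted p was 0.406, 0.0672 and 0.539 for these 3 lists. Of 86 ribosomal protein genes, 0 rose and 1 fell (0 up and 0 down adjusted over the list alone), the muscle-specific Rpl3l at -3.50. Rps7 stood at -0.96, not past the test (edgeR adjusted p = 0.114). The list was called down (camera adjusted p = 0.0221, and 0.695 with an estimated correlation). It was not called without Control tissue-3 (0.742), YAP5SA tissue-1 (0.336) or YAP5SA tissue-2 (0.107). With library totals alone the medians of the ribosomal, antioxidant and immediate early lists turned from -0.33, -0.35 and -0.13 to 0.52, 0.51 and 0.71, each below the median of all genes of 0.88 there. Of the marker lists, those of cardiomyocytes (9 of 14 fell, median -2.63), macrophages, smooth muscle (median 0.87, 3 of 7 rose) and epicardium (median 3.18, 3 of 6 rose) were called by camera. They had adjusted p = 2.03e-06, 0.00389, 0.00914 and 0.00389, and 0.379, 0.724, 0.379 and 0.379 with an estimated correlation. Those of fibroblasts, endothelium, endocardium, monocytes and pericytes had medians of 0.78, 0.41, 1.72, -0.58 and 0.23 and camera adjusted p from 0.207 to 0.959. The other 7 marker lists had under 3 members tested.

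A further comparison asked which of these effects differed between cardiomyocytes, where the transgene is switched on, and the other cells of the same hearts. The rise of Csf1 was larger in cardiomyocytes than in fibroblasts by 3.91 on the log2 scale (edgeR adjusted p = 1.13e-10) and than in macrophages by 3.20 (0.0143). In the same order it was larger for Mki67 by 3.30 and 3.93 (1.71e-06 and 1.90e-05), and for Crim1 by 2.80 and 2.48 (1.92e-05 and 0.00337). The change of Sdhb was lower in cardiomyocytes than in fibroblasts by a difference of -2.33 and than in macrophages by -2.38 (edgeR adjusted p = 0.00127 and 0.00197). For Pln and Tnni3 the difference was -0.33 and -0.13 against fibroblasts and did not pass (edgeR adjusted p = 0.756 and 0.919). The genes counted here as risen or fallen were called in the cardiomyocytes of the same libraries, which favours a larger effect there. Leaked RNA of other cells was not told apart from such differences. Against fibroblasts the effect was higher in cardiomyocytes for 35 of the 38 G2/M genes that rose there, 14 of the 17 S phase genes and 12 of the 13 YAP targets. Over all tested members it was higher for 37 of 54 G2/M, 15 of 43 S phase and 13 of 21 YAP target genes. Against fibroblasts the effect was lower for 33 of the 44 oxidative phosphorylation genes that fell, but for 0 of the 11 sarcomere genes that fell. Sarcomere RNA in the other classes followed the cardiomyocytes of the same library, with a median Spearman correlation of 0.945 over genes. It may be free RNA, so the lack of a difference does not show that these genes fell within the other cells. Of the raised G2/M genes the effect was higher than in macrophages for 35 of 38, in monocytes for 14 of 38, in endothelial for 25 of 34, in endocardial for 16 of 29, in epicardial for 20 of 32 and in smooth muscle cells for 5 of 25. Of the raised S phase genes it was 11 of 17, 6 of 17, 5 of 15, 7 of 13, 4 of 13 and 1 of 11 in the same order. Of the YAP targets it was 9, 6, 10, 9 and 10 of 13 and 6 of 12. The effect was lower in cardiomyocytes for 39, 36, 39, 37, 21 and 33 of the 44 oxidative phosphorylation genes, and for 0 of the 11 sarcomere genes in each of these classes but smooth muscle cells (1). In all, the effect differed between cardiomyocytes and fibroblasts for 2161 of 12402 genes, 1295 of them higher and 866 lower in cardiomyocytes. This balance depends on the scaling and the libraries: it was 2869 higher and 109 lower with library totals alone, 602 and 105 without YAP5SA tissue-2, 653 and 155 without YAP5SA tissue-1, 1163 and 1253 without Control tissue-2, and 1116 and 1227 without YAP5SA enriched. It differed for 1734 genes against macrophages, 933 against monocytes, 1550 against endothelial, 938 against endocardial, 662 against epicardial and 683 against smooth muscle cells. Each count fell to less than its main value divided by 1.5 without Control tissue-3 (1142, 522, 160, 495, 238, 85 and 155 genes in that order). The same held without YAP5SA tissue-1 (808, 801, 242, 729, 366, 378 and 404) and without YAP5SA tissue-2 (707, 1111, 288, 907, 335, 326 and 329). The count against smooth muscle cells did so without Control enriched (383).

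The next comparison asked whether cells that do not express the Myh6-driven Cre differed between genotypes. In fibroblasts 155 genes rose and 82 fell of 10761 tested. This balance was 122 and 28 with RLE size factors, 24 and 2 with library totals alone, and 38 and 56 without processed pseudogenes. Prg4, lubricin, a secreted glycoprotein, went from 324 ± 393 to 3289 ± 1777 CPM (n = 3 libraries each; log2 fold change 3.55, SE 0.98, edgeR adjusted p = 0.0203), and Mgam, an intestinal glucosidase, rose by 3.21. The lipase inhibitor G0s2 changed by -2.26, but by -0.37 between the 4 libraries with joined names. Of the genes that rose, 111 are processed pseudogenes, such as Gm7331 (4.91), Gm8203 (3.06) and Rpl27-ps2 (3.02), and 10 others were highest in fibroblasts among the 8 classes. Of the genes that fell, 44 were highest in cardiomyocytes, such as Pln (-3.39), Tcap (-3.25), Fabp3 (-2.89), Cox7a1 (-2.77) and Xirp2 (-2.60), and 69 lay more than 5-fold below their level in another class. The count of 237 was 26 by DESeq2, 0 with the tissue libraries alone, and 0 with at least 30 cells per library, which leaves out the 10 fibroblasts of Control enriched. It was 424 with the way of annotation as a further term, and 646 in the 4 libraries with joined names. Leaving out 1 library gave 0 genes without Control enriched and without YAP5SA enriched, 3 without YAP5SA tissue-2, 7 without YAP5SA tissue-1, 664 without Control tissue-3 and 1160 without Control tissue-2.

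Camera called 9 of 20 lists in fibroblasts. Sarcomere genes (9 of 25 fell, median -1.51), fatty acid oxidation genes (3 of 23 fell, -0.65), oxidative phosphorylation genes (3 of 45 fell, -0.30) and fetal cardiac genes (2 of 10 fell, -0.33), all of them abundant in heart muscle, were lower. In that order 14, 5, 3 and 3 members were down adjusted over the list alone. Also lower were mitochondrially encoded genes (-1.62, 0 of 9 past the test) and immediate early genes (-0.55, 1 of 32 fell, Fosb at -2.61). Btg2 stood at -2.38 (edgeR adjusted p = 0.0597), and 3 and 6 members were down adjusted over the list alone. S phase (0.31), G2/M (0.33) and interferon response genes (0.90) were higher as lists with no member past the test. Cks2, a partner of the cyclin-dependent kinases, had 1.54 and Top2a, a topoisomerase, 1.14 (edgeR adjusted p = 0.155 and 0.861). In these lists 0, 0 and 1 members passed adjusted over the list alone. The camera adjusted p ran from 1.07e-33 for sarcomere to 0.0130 for fetal cardiac genes, and from 0.400 to 0.862 with an estimated correlation. Among marker lists those of cardiomyocytes (median -2.55, 9 of 14 fell) and of endothelium (-1.79, 4 of 9 fell) were lower. They had camera adjusted p = 3.12e-33 and 1.51e-06, and 0.270 and 0.282 with an estimated correlation.

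In macrophages and monocytes no single gene passed in the main fit. With the way of annotation in place of preparation as a term, 81 and 1 did. Macrophages had lower values of Atf3, an immediate early factor (-3.45, edgeR adjusted p = 0.0959), and of Igf1 (-1.81, 0.0791), neither past the test. The same held for the matrix genes Col1a2 (-1.62, 0.138) and Col4a1 (-1.66, 0.279) and the sarcomere genes Csrp3 (-3.20, 0.0694) and Actc1 (-2.73, 0.0774). Markers of fibroblasts (-1.78), endothelium (-2.12) and pericytes (-1.80) were lower there as lists too, with camera adjusted p = 0.000144, 2.49e-06 and 0.0295, and adjusted p = 0.519 for each with an estimated correlation. The lower matrix genes are therefore not told apart from less free RNA of these cells. Monocytes had Dusp1 at -1.91 (edgeR adjusted p = 0.461), the chemokine Ccl4 at -1.82 (0.460) and Cenpf, a kinetochore protein, at 1.82 (0.486). By edgeR 0 of 11806 genes were called in macrophages, with 1183 at an unadjusted p under 0.05 and 98 called by DESeq2. In monocytes edgeR called 0 of 3506, with 280 and 23. Control enriched held neither class, so 2 Control and 3 YAP5SA libraries entered. With preparation as a term, YAP5SA enriched, then the only enriched library, adds nothing to the genotype effect. The effect thus rests on 2 against 2 tissue libraries. The same holds for epicardial cells, of which Control enriched had only 7. Camera called 10 of 20 lists in macrophages. Immediate early (median -1.14, 15 of 32 down adjusted over the list alone), sarcomere (-1.97, 4 down adjusted over the list alone), matrix (-0.76), both mitochondrial lists (-2.27 and -0.38), fatty acid oxidation (-0.69), antioxidant (-0.18) and cytokine genes (-0.14, 2 down adjusted over the list alone) were lower. S phase (0.25) and ribosomal genes (0.37, with a mean of -0.01) were higher. The camera adjusted p ran from 1.77e-12 to 0.0488 and from 0.676 to 0.750 with an estimated correlation. It called 9 of 19 in monocytes. Sarcomere (-2.76, 13 of 18 down adjusted over the list alone), immediate early (-1.36, 1 down), both mitochondrial lists, fatty acid oxidation, matrix and cytokine genes were lower. G2/M (0.49) and interferon response genes (0.96) were higher. All had adjusted p = 0.732 with an estimated correlation. In macrophages and monocytes leaving out YAP5SA tissue-1 gave 94 and 0 genes, and YAP5SA tissue-2 52 and 0, with 1 YAP5SA tissue library left to set the effect. Leaving out Control tissue-2 or tissue-3 left 1 Control library, so no count of genes is given. Without Control tissue-2 the genotype also went with the way of annotation among the tissue libraries, since Control tissue-3 has no joined names.

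In the cells of the vessels and the heart's linings no gene passed by edgeR either. Endothelial cells had lower Atf3 (-2.51) and Fos (-2.31), immediate early factors, and lower Fabp3 (-2.64), the fatty acid binding protein of heart muscle, each at edgeR adjusted p = 0.113. They had higher Eln, elastin (1.79, 0.164), and Capg, an actin-capping protein (2.14, 0.185), none past the test. Epicardial cells had the chemokine Ccl12 at 3.13 (edgeR adjusted p = 0.326), endocardial cells Pln at -3.88 (0.690). Smooth muscle cells had the sarcomere light chains Myl2 at -2.24 (0.721) and Myl3 at -2.39 (0.756). The edgeR count was 0 of 5360 genes in endothelial cells (540 at an unadjusted p under 0.05, 33 by DESeq2), 0 of 1991 in endocardial cells (107 and 1), 0 of 1818 in epicardial cells (106 and 0) and 0 of 995 in smooth muscle cells (48 and 0). Camera called 9 lists in endothelial cells, with sarcomere (-1.59), fatty acid oxidation (-1.05), oxidative phosphorylation (-0.48) and immediate early genes (-0.49) lower. Higher were S phase (0.57), G2/M (0.55), matrix (0.55), actin (0.49) and ribosomal genes (0.32). Adjusted over the list alone, 7 sarcomere, 10 fatty acid oxidation, 1 oxidative phosphorylation and 12 immediate early genes were down there. On the same terms 1 immediate early, 1 S phase, 2 matrix and 2 actin genes were up. The estimated correlation gave adjusted p from 0.614 to 0.703. Sarcomere, oxidative phosphorylation and fatty acid oxidation genes were also lower in endocardial (-1.95, -0.45 and -0.88), epicardial (-2.26, -0.34 and -0.79) and smooth muscle cells (-1.32, -0.33 and -0.63). In the same order 5, 0 and 1, 3, 0 and 0, and 6, 0 and 0 members were down adjusted over the list alone. The rest of the 4, 5 and 8 lists called were ribosomal genes in endocardial cells and complement genes and cytokines in epicardial cells (all higher), and actin, complement and unfolded protein response genes (higher) and mitochondrially encoded and immediate early genes (lower) in smooth muscle cells. The estimated correlation gave adjusted p from 0.811 to 0.883, of 0.933 and of 0.609. Cardiomyocyte markers were lower as a list in each of the 7 other classes, with medians from -3.04 in monocytes to -1.96 in smooth muscle cells and camera adjusted p from 3.12e-33 to 8.31e-07. These lists had adjusted p from 0.270 to 0.519 with an estimated correlation, and outside fibroblasts no member passed by edgeR. Macrophage markers were higher as a list in endothelial (1.12), epicardial (1.22) and smooth muscle cells (1.36), with camera adjusted p = 0.00167, 1.35e-08 and 1.18e-05. They had adjusted p = 0.505, 0.124 and 0.401 with an estimated correlation, and no member passed by edgeR. Leaving out Control tissue-2 gave 80 genes in endothelial, 12 in endocardial and 1 in smooth muscle cells, and Control enriched or YAP5SA enriched 2 in endothelial cells. For epicardial cells, leaving out Control tissue-2 or tissue-3 left 1 Control library, so no count of genes is given.

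The fourth comparison asked how the cell classes were shared out in the libraries of each genotype, within a preparation. Settling sets the share of cardiomyocytes in the enriched libraries. In the tissue libraries the cardiomyocyte and other fractions were put together again. The shares in either preparation thus need not be those of the heart. Macrophages made up 47.3% of the cells of YAP5SA tissue-1, 53.1% of YAP5SA tissue-2 and 40.0% of YAP5SA enriched. They made up 20.6% of Control tissue-2, 4.75% of Control tissue-3 and 0 of the 1405 cells of Control enriched, which allows a share of up to 0.214%. Cardiomyocytes made up 8.92% and 4.81% of the YAP5SA tissue libraries and 22.0% of YAP5SA enriched, against 19.8%, 37.6% and 76.0% in Control. Fibroblasts made up 33.9%, 33.0% and 27.4% of the YAP5SA libraries and 50.3%, 13.3% and 0.712% of Control tissue-2, tissue-3 and enriched. The difference of the mean shares, YAP5SA minus Control, was 38.3 percentage points for macrophages, -32.6 for cardiomyocytes, 2.05 for monocytes and -1.19 for smooth muscle cells (n = 3 libraries each, exact two-sided permutation within preparation, p = 0.167 for each, the smallest its 12 arrangements allow). It was 9.97 for fibroblasts (exact permutation p = 0.5), -12.9 for endothelial (0.333), -2.63 for endocardial (0.5) and -1.05 for epicardial cells (0.333). Between the tissue libraries alone it was 37.5 for macrophages and -21.8 for cardiomyocytes (exact permutation p = 0.333 for each), and 1.64 for fibroblasts (p = 1). With cells other than cardiomyocytes as the denominator it was -39.2 for endothelial (exact permutation p = 0.167), -5.53 for endocardial (0.333), -2.29 for epicardial (0.167), -3.39 for smooth muscle cells (0.167) and 6.64 for fibroblasts (0.667). Without Control enriched it was -16.8 for cardiomyocytes, 1.22 for monocytes, -0.390 for fibroblasts, -3.97 for endocardial and -1.68 for epicardial cells. Without Control tissue-2 it was 24.4 for fibroblasts, -19.6 for endothelial and -4.02 for endocardial cells, and without Control tissue-3 5.91 for fibroblasts, -7.95 for endothelial, 0.103 for endocardial, -0.168 for epicardial and -0.671 for smooth muscle cells. The clusters were drawn by the authors over all libraries, and 8 shares that sum to 100% cannot move on their own.

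**Figure D4:**
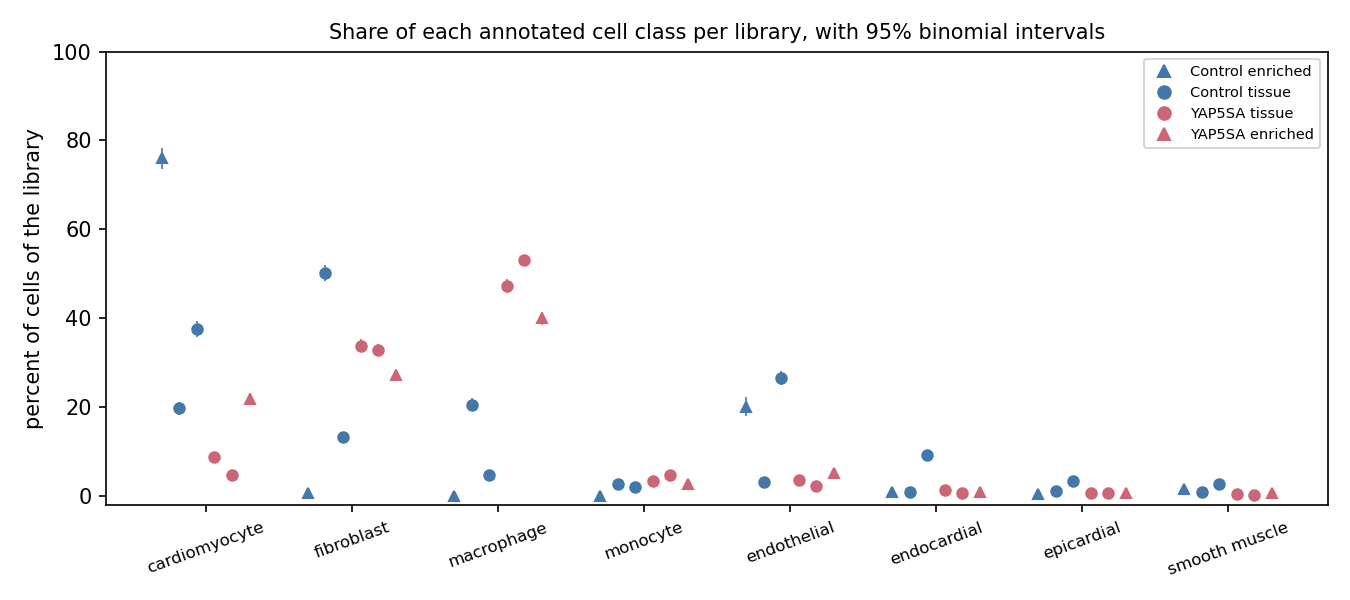
Percent of the cells of each library in the 8 annotated cell classes, with exact 95% binomial intervals for counting error. Macrophages are at 40.0% to 53.1% in the YAP5SA libraries and at 0 to 20.6% in the Control libraries.

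The last comparison asked how many cardiomyocytes held cell cycle transcripts, after thinning each cell to 1000 UMIs. Among cardiomyocytes with that depth 82.1% ± 2.51 of YAP5SA and 67.0% ± 12.99 of Control cells held at least 1 UMI of an S or G2/M phase gene (mean ± SD, n = 3 libraries each), a difference of 15.1 points (exact two-sided permutation p = 0.333). Smooth muscle cells, taken as a class that mostly does not divide, held such a UMI in 86.4% ± 3.96 and 83.7% ± 0.550 of cells, at median depths before thinning of 1213.5 to 1879.5 UMIs against 1876 to 4595 in cardiomyocytes. The share in cardiomyocytes lay below this in both genotypes. A UMI of the full lists thus does not mark a cycling cell. Of the list genes, 56 were seen in at most 2% of smooth muscle cells, a selection made after the shares were seen. With these, a mean of 27.8% of YAP5SA and 6.33% of Control cardiomyocytes held a UMI, a difference of 21.5 points (exact permutation p = 0.167). In smooth muscle cells the means were 23.2% and 17.2%. On this measure the libraries of YAP5SA tissue-1, tissue-2 and enriched had 24.7% (exact 95% interval 19.8 to 30.1), 39.6% (33.4 to 46.0) and 19.1% (16.6 to 21.9). Control enriched, tissue-2 and tissue-3 had 5.24% (3.97 to 6.77), 5.71% (3.94 to 7.97) and 8.04% (6.54 to 9.77). All 3 YAP5SA libraries thus lay above all 3 Control libraries. YAP5SA enriched was near the smooth muscle cells of the same library, whose share was 19.2%, of at most 34 cells. Smooth muscle cells are no measured background for cardiomyocytes, since the genes were picked as rare in them. Control cardiomyocytes also lay below them. No share of cycling cardiomyocytes is read from these values. Intervals and limits for a count of 0 cover counting error only.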

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

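The tests of other-cell RNA, of scaling, of annotation, of free cardiomyocyte RNA and of pseudogenes were chosen only after the results were seen, as were the tests by splits of the libraries for genes within 1 class; those for gene lists and for differences between classes were chosen before.

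S and G2/M phase genes such as Mki67, Anln and Rrm2 were higher in YAP5SA cardiomyocytes, and macrophages made up 40.0% to 53.1% of the cells of YAP5SA libraries against 0 to 20.6% in Control. Leakage of RNA from cycling macrophages and fibroblasts into cardiomyocyte droplets was weighed. In cardiomyocytes without a UMI of 27 macrophage and fibroblast markers, the 55 raised genes stood at 963, 2192 and 865 CPM in the YAP5SA libraries (92, 49 and 545 UMIs in 61, 16 and 312 cells). They stood at 82.2, 119 and 83.6 CPM in Control (192, 28 and 88 UMIs in 885, 102 and 299 cells), the lowest over the highest being 7.27-fold. This does not decide it, since free RNA can reach a droplet without a marker UMI, and YAP5SA libraries held more macrophages. Over all cardiomyocytes of YAP5SA tissue-1, tissue-2 and enriched the median level of these genes was 3.93, 2.75 and 1.68 times what leakage would give if all of it came from cycling clusters. The same ratio was 0.382 in Control tissue-2 and 0.0588 in Control tissue-3. The 55 genes were picked as higher in the same YAP5SA libraries, which favours high ratios there. For these genes the level thus lay above that of such leakage, but the ratios do not exclude leakage as a source. A fall of abundant cardiomyocyte transcripts that lifts all other genes does not account for the rise, since with library totals alone the lists' median exceeded that of all genes by 2.86. Nor do the 2 ways of annotation on their own, with a median of 2.99 in the 4 libraries with joined names. The other pair, 1 library each, had 1.83. Both comparisons mix preparation with genotype, since among the joined-name libraries the enriched one is Control and those of YAP5SA are from tissue. Without the cells of the cluster YAP5SAcm the median was 0.31 against 2.94 with them, which decides nothing, since the authors drew the cluster from the same transcripts, and doublets with cycling cells were not removed. An effect of the activated YAP on the cell cycle genes of cardiomyocytes may account for it, as a hypothesis found and tested on the same libraries, with doublets left open and no count of dividing cells.

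As a list, sarcomere genes had medians from -2.76 to -1.32 in the 7 other classes of YAP5SA libraries, called by camera with its preset correlation in each, with adjusted p from 0.400 to 0.933 with an estimated correlation. By edgeR 9 of them, Pln included, fell in fibroblasts, and no gene passed in the other 6 classes (48 to 1183 genes at an unadjusted p under 0.05, and 0 to 98 by DESeq2). Free cardiomyocyte RNA in the droplets of other cells may give this: over 25 sarcomere genes the profile of the other classes had a median Spearman correlation of 0.945 with the cardiomyocytes of the same library (39 pairs of class and library, 0.771 to 0.991; across genes, which are not independent replicates). Over all cells of a library the sarcomere genes held 131201, 69401 and 94503 CPM (unscaled) in Control enriched, tissue-2 and tissue-3 and 14744, 7407 and 39351 in YAP5SA tissue-1, tissue-2 and enriched. A lower expression of these genes in the other cells was not tested apart from it.

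Processed pseudogenes were higher in the other classes of YAP5SA libraries, with a median log2 fold change of 0.88 in fibroblasts and 1.05 in macrophages against 0.07 and 0.01 for other genes. In cardiomyocytes their median was -0.02, with 26 higher and 28 lower, and outside fibroblasts and cardiomyocytes no pseudogene passed by edgeR. Reads split differently between ribosomal genes and their pseudogenes from library to library could give this: over 240 pseudogenes of 54 parents the log2 ratio to the parent was -2.65, -2.13 and -4.26 in Control enriched, tissue-2 and tissue-3 and -1.94, -2.16 and -3.48 in YAP5SA tissue-1, tissue-2 and enriched. Its range between libraries was 2.28 times the largest range between classes of 1 library, 1.02 in Control enriched, which held 10 fibroblasts, while that of the other 5 libraries was at most 0.266. The threshold of 4 set for this ratio was chosen after preliminary values, and the explanation stays open, since the ratio lies below it and the ratios per library in cardiomyocytes (-2.72, -2.06 and -4.24 in Control, -2.04, -2.24 and -3.45 in YAP5SA) are close to those in the other classes, apart from Control enriched, although their pseudogenes did not move one way.

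The effect of the genotype differed between cardiomyocytes and another class, by the class by genotype term, for 2161 genes in fibroblasts, 1734 in macrophages, 933 in monocytes, 1550 in endothelial, 938 in endocardial, 662 in epicardial and 683 in smooth muscle cells. The authors' phase calls, which no comparison uses, put 13.7%, 19.1% and 13.8% of the cardiomyocytes of YAP5SA tissue-1, tissue-2 and enriched outside G1, against 1.74% to 3.75% in Control, 4.55% to 17.6% of smooth muscle cells and 47.3% to 71.3% of macrophages, and no cycling is read from them, since free RNA enters such calls. Egfp, a feature outside the comparisons, had 382 and 426 UMIs over all cells of YAP5SA tissue-1 and tissue-2. Cardiomyocytes held 253 and 305 of them (239 and 242 CPM, unscaled), fibroblasts 63 and 47 (30.7 and 10.1 CPM) and macrophages 39 and 47. Endothelial cells held 15 and 10 (68.3 and 50.8 CPM) and endocardial cells 9 and 8 (107 and 74.9 CPM). The other 4 libraries held 0 in any class. One of these, YAP5SA enriched, has no joined names, and whether its reference held Egfp, or where Egfp comes from, was not settled from the files.

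With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes, 1 of the 10 splits of the 6 libraries gave as many as the real 2889 in cardiomyocytes (highest other 0), 2 gave as many as 237 in fibroblasts (highest other 1032), and all 10 gave as many as 0 in endothelial, endocardial and smooth muscle cells (highest other 8, 24 and 2). The split with 1032 fibroblast genes puts Control tissue-2 with the YAP5SA tissue libraries, and on the other side both enriched libraries and both without joined names. With preparation as a term, its effect is set by the tissue libraries alone. These are Control tissue-3 against Control tissue-2, YAP5SA tissue-1 and YAP5SA tissue-2, which also differ from it in annotation. For lists, the numbers were 1 in cardiomyocytes (17 real, highest other 15), 8 in fibroblasts (9 and 12), 5 in endothelial (9 and 11), 7 in endocardial (4 and 10) and 3 in smooth muscle cells (8 and 9). For genes whose effect differs from cardiomyocytes, it was 1 each for fibroblasts (2161 real, highest other 0), endothelial (1550 and 0), endocardial (938 and 9) and smooth muscle cells (683 and 23).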

How the results depend on the processing

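Alternatives on joined names, ways of annotation, pseudogenes and the cluster YAP5SAcm were chosen after seeing the data, as was the restricted cycle list. No paired analysis was possible because the table of cells numbers the YAP5SA tissue libraries 1 and 2 and the labels number them 2 and 3, so the planned replicate-block variants for genes, lists, shares, cycle transcripts and differences between classes were not run. In cardiomyocytes the direction of all 74 named called genes was kept under every alternative that tested them, and Acta1 in fibroblasts reversed, with 1.70 between the single pair of libraries without joined names; the cause was not tested. On simulated data with 200 changed genes, 1.5% to 25.4% of 2-fold changes were recovered over the 8 classes. Where as few genes change, most changes of that size are thus missed at this depth and number of libraries.

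Gene counts in cardiomyocytes (2889) were 4543 with library totals alone, 1763 in tissue libraries alone, 1183 in the 4 joined-name libraries and 17 without the cluster YAP5SAcm, and 198 (without YAP5SA tissue-2) to 4595 (without Control tissue-2) with 1 library left out. In fibroblasts (237) they were 150 with RLE factors, 26 with totals alone, 26 by DESeq2, 36 without the covariate, 0 in tissue libraries alone, 1 with equal numbers of cells, 0 with at least 30 cells, 22 with features as deposited, 424 with the annotation as a further term, 646 in joined-name libraries and 94 without processed pseudogenes, and 0 to 1160 with 1 library left out. The other classes had 0 by edgeR, with the counts at an unadjusted p under 0.05 being 1183 in macrophages, 280 in monocytes, 540 in endothelial, 107 in endocardial, 106 in epicardial and 48 in smooth muscle cells. By DESeq2 they had 98, 23, 33, 1, 0 and 0, and with no filter on low counts 492, 113, 251, 22, 31 and 14. With the annotation as a further term the count was 303 in macrophages, 97 in monocytes and 6 in epicardial cells, and with it in place of the preparation 81 in macrophages and 1 in monocytes. Monocytes had 1 gene without the covariate, and endothelial cells 14 with totals alone, 1 in tissue libraries alone and 1 without processed pseudogenes. With 1 library left out the counts ran from 0 to 1105 in macrophages, 0 to 612 in monocytes, 0 to 80 in endothelial, 0 to 12 in endocardial, 0 to 160 in epicardial and 0 to 1 in smooth muscle cells, each highest without Control tissue-2; the cause of these changes was not tested.

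Of the 17 lists called in cardiomyocytes, 0 were called with an estimated correlation and 10 by fry; in each of the other 7 classes both gave 0. With the annotation as a further term 3 lists were called in macrophages and 4 in monocytes, tissue libraries alone gave 5 in endothelial and 3 in smooth muscle cells, and joined-name libraries 4 in smooth muscle cells. With 1 library left out the number ran from 3 to 11 in macrophages, 5 to 12 in monocytes, 5 to 13 in endothelial, 4 to 8 in endocardial, 1 to 9 in epicardial and 3 to 9 in smooth muscle cells. Differences of the effect from cardiomyocytes numbered, with totals alone, 2790 in endothelial, 1559 in endocardial, 1172 in epicardial and 1221 in smooth muscle cells. With 1 library left out they ran from 707 to 2416 in fibroblasts, 522 to 2065 in macrophages, 160 to 1131 in monocytes, 495 to 2269 in endothelial, 238 to 1134 in endocardial, 85 to 631 in epicardial and 155 to 798 in smooth muscle cells. The difference of shares ran from -0.390 (without Control enriched) to 24.4 points in fibroblasts and from -4.02 to 0.103 (without Control tissue-3) in endocardial cells. It ran from -44.9 to -16.8 in cardiomyocytes, 1.22 to 2.66 in monocytes, -19.6 to -7.95 in endothelial, -1.68 to -0.168 in epicardial and -1.60 to -0.671 in smooth muscle cells; the cause was not tested. For cell counts per class edgeR called 0 of 8 (1 at an unadjusted p under 0.05, macrophages, log2 fold change 3.48, lowest adjusted p = 0.247). The difference of cells with cycle transcripts was 2.38 points without thinning, 19.3 at 500 UMIs, 12.2 for S and 19.6 for G2/M genes alone, 23.1 for at least 2 UMIs and 12.1 without the cluster YAP5SAcm.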

Other observations

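In macrophages camera with its preset correlation called 5 marker lists of other cell types lower, and an estimated correlation called none. The markers of cardiomyocytes had a median log2 fold change of -2.69 there, those of endothelium -2.12, fibroblasts -1.78, pericytes -1.80 and T or NK cells -1.69, with camera adjusted p = 3.51e-08, 2.49e-06, 0.000144, 0.0295 and 0.0365, and adjusted p = 0.519 for each with an estimated correlation; no single gene passed by edgeR (1183 at an unadjusted p under 0.05, 98 by DESeq2). Erythroid markers had a median of 1.69 in macrophages and -0.86 in endothelial cells (camera adjusted p = 0.821 and 0.574). Markers of lymphatic endothelium, neutrophils, B cells, Schwann cells and adipocytes had under 3 tested members in every class.

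Ankrd1, a YAP target and a gene of stressed heart muscle, had 15241 CPM (unscaled) in the cardiomyocytes of Control tissue-2, against 2478 and 2199 in Control enriched and tissue-3 and 21128, 20624 and 16758 in YAP5SA tissue-1, tissue-2 and enriched. Nppb, a natriuretic peptide, had 7688 in Control tissue-2 against 614 and 343, and 5068, 6543 and 5070 in YAP5SA. Both were chosen after their values were seen. Xist, expressed from the inactive X chromosome of female cells, had 154 UMIs in Control enriched and 1800 in YAP5SA tissue-1, and at most 1 in each of the other 4 libraries. Y-linked genes had 1 and 3 UMIs in these 2 libraries and 1102 to 2875 in the others. By these counts Control enriched and YAP5SA tissue-1 came from female hearts and the others from male ones. Sex was not a term in any fit. In the enriched pair it is not told apart from genotype, and among the tissue libraries only YAP5SA tissue-1 was female.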
